A study of Mus musculus with 8 samples.

How the data were processed

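Naive T cells, gated as CD62L-positive and CD44-low, were sorted from mesenteric lymph nodes and spleens of 4-week-old mice, per the labels. The labels abbreviate the nodes as mLNs. The mice were wild type (WT) or carried a conditional knockout (KO) of Trappc1 driven by CD4-cre, a Cre recombinase switched on in developing T cells that deletes a gene flanked by its target sites in both the CD4 and the CD8 lineage. RNA was extracted with TRIzol and libraries were made with a SMARTER mRNA kit, per the labels. The part of Trappc1 that is deleted is not given in the sources used here. There were 8 libraries in 4 groups of 2, namely CD4 WT, CD4 KO, CD8 WT and CD8 KO, grouped by the cell type and genotype in the labels.

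Reads were aligned with HISAT to the mouse build mm10, per the submitters' processing notes, and the version and the program that made the gene tables are not given in the sources used here. Each library comes with a table of 23337 gene symbols with positions. Per the file headers, the deposited tables give TPM, a length-corrected share of transcripts, which the authors scaled to the same total in every library. The deposited tables also give FPKM per gene, a length-corrected fragment density, per the file headers. A coverage column per gene is deposited as well, per the file headers, and was used here to estimate depth. The labels name DESeq2 as the tool the authors used for differential expression, but no read counts were used here, since the tables hold none. Symbols listed on several rows, at most 261 in a library, were summed. No mitochondrially encoded messenger RNA is listed in the tables.

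Depth was estimated from the ratio of coverage to FPKM, which lay within 1% of 1 value for 84.7% to 86.4% of the genes in each library and gives the aligned bases. It ranged from 3.03 to 4.01 gigabases. Because TPM keeps no read counts, no counting interval can be given for a gene, and a gene listed at 0 may be one that the estimate missed. Between 5952 and 10634 symbols were listed at 0 per library, so a 0 is reported as listed and no fold is drawn from a group in which both libraries are at 0.

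The design fixed before the data were examined assumed read counts and named limma on log2 values for the case that only normalised values were given, and that second choice was used. Genes with a mean of at least 1 TPM over the 8 libraries were kept, leaving 11786. TPM plus a pseudocount of 1 was taken to the log2 scale and fitted with limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with an intensity trend, 1 mean per group and a spread pooled over the 4 groups, which leaves 4 residual degrees of freedom and a prior of 5.68. Each log2 difference is on the log2(TPM + 1) scale, which understates changes of weakly expressed genes. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Every adjusted p below is from limma or, for gene lists, from limma's camera unless another test is named. The comparisons were KO against WT in CD4 cells, the same in CD8 cells, the difference between those effects, and WT CD8 against WT CD4 cells. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these libraries, which may be technical.

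The steps were tested on simulated data made from the real genes, for the CD4 comparison over 11786 genes. The changed genes were drawn only from those well expressed in CD4 WT, so recovery of weaker genes was not tested. Of 67 genes changed by 1 on the log2 scale 0 were recovered, of 67 changed by 2 it was 29 (43.3%), and of 66 changed by 3 it was 52 (78.8%), with 3 false calls. Changes of 2-fold are therefore mostly out of reach of this design.

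A total of 34 gene lists were fixed before the data were examined, covering secretory transport, stress and death pathways, metabolism, T cell states and markers of other cell types. They hold 762 distinct genes, some of them in several lists. Of these genes 18 were matched through older symbols in a RefSeq table of GRCm38.p6 and 24 are absent from the files. The 33 lists with at least 3 measured members were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. It was repeated with the correlation estimated from the residuals, and with fry, which asks whether a list's own genes move on balance one way. Counts of members that passed are given over all genes and, where stated, adjusted over the list alone.

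Genes named in the text were chosen by a rule fixed in advance, with TPM standing in for the planned count-based unit. It takes, for each KO comparison, the 8 largest rises and the 8 largest falls among called genes whose KO and WT libraries do not overlap and whose higher group averages at least 5 TPM. It adds up to 2 called members of each list, Trappc1, the lineage genes Cd4, Zbtb7b, Cd8a, Cd8b1 and Runx3 with the 3 largest differences each way for the WT comparison, and the 3 lowest p-values for the difference of effects. Predicted and Riken gene symbols and receptor segments were left out of the naming. Genes named outside the rule are said to be so.

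Other settings fixed in advance were no filter on low values, a pseudocount of 0.1, fits of the compared groups alone, the replicate number as a block, a minimum absolute log2 difference of 1, and leaving out each library in turn. Added after seeing the data were FPKM in place of TPM, median-of-ratios scaling, quantile normalisation, limma's library weights, removal of a trend with genomic span, and a list-by-list account of the setting without the library labelled CD8 WT replicate 2. Settings fixed in advance that need read counts could not be run.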

Results

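Messenger RNA of naive CD4 and CD8 T cells was sequenced from WT mice and from mice whose T cells carry a deletion in Trappc1, with 2 libraries in each of the 4 groups. Trappc1 encodes a core subunit of the TRAPP complexes, which tether transport vesicles at the Golgi apparatus. The series title puts the question as whether naive T cells need this gene to survive. Aligned sequence was 3.74 and 3.48 gigabases for CD4 WT, 3.03 and 3.22 for CD4 KO, 3.78 and 3.57 for CD8 WT, and 4.01 and 3.52 for CD8 KO. Replicates correlated across genes with Pearson's r of 0.944 in CD4 WT, 0.951 in CD4 KO, 0.929 in CD8 KO and 0.821 in CD8 WT.

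The library labelled CD8 WT replicate 2 stood apart from the other 7. The haemoglobin gene Hba-a1 made up 7.73% of its transcripts, at 77329 TPM against 33.3 in replicate 1, and the neutrophil granule gene Ngp stood at 17333 TPM against 330. The antigen-presentation gene Cd74, which B cells express, was at 11372 TPM against 523, with 2719 to 7008 TPM in the CD4 libraries. The B cell gene Cd79a stood at 336 TPM, above the other CD8 libraries (118 to 157) and below the CD4 libraries (494 to 812). The T cell genes Cd8a (163 against 548 TPM) and Cd3d (190 against 504 TPM) were lower than in replicate 1. The first principal component, with 30.6% of the variance, separated this library, and the next set the 4 KO libraries below the 4 WT libraries. Hba-a1 is a near-identical copy of Hba-a2, so the division of reads between them is uncertain.

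**Figure D1:**
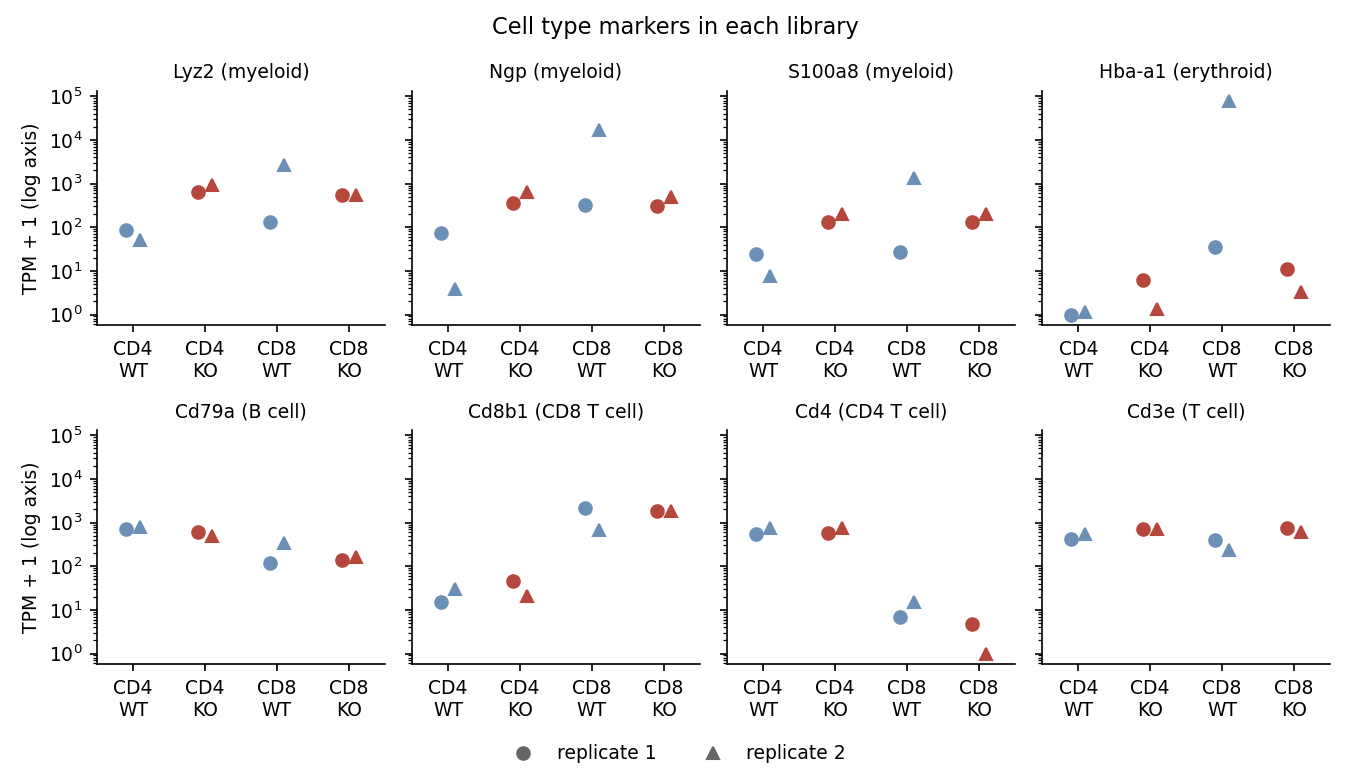
TPM + 1 on a log axis for markers of myeloid, erythroid, B and T cells in each of the 8 libraries (points, by replicate; red KO, blue WT). The library labelled CD8 WT replicate 2 holds the highest Lyz2 (2651 TPM), Ngp and Hba-a1, and the KO libraries hold 543 to 926 TPM of Lyz2 against 49.0 to 131 in the other WT libraries.

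Trappc1 itself (chromosome 11, 69323986 to 69325793, plus strand, mm10, positions as the files give them) was measured in every library. It stood at 78.7 and 55.0 TPM in CD4 WT, 30.5 and 32.8 in CD4 KO, 81.2 and 40.3 in CD8 WT, and 56.9 and 45.6 in CD8 KO. The CD4 KO difference was -1.03 ± 0.40 on the log2 scale (SE), with both KO libraries below both WT libraries, but it did not pass (limma, adjusted p = 0.235). It passed in 1 of 17 other settings, with limma's library weights (adjusted p = 0.0440). The CD8 difference was -0.16 ± 0.40 (adjusted p = 0.869). The library labelled CD8 WT replicate 2 lay below both CD8 KO libraries, against its label, though with median-of-ratios scaling it lay between them (49.4 against 55.6 and 45.8 scaled TPM). Without it the CD8 difference was -0.66 (adjusted p = 0.376). The files give 1 value per gene and not per exon, so this is no check of the deleted part. Of the 13 other TRAPP subunits, 0 passed in CD4 and 0 in CD8 cells by limma, with 2 at an unadjusted p under 0.05 in each, and the list did not pass camera (adjusted p = 0.526 and 0.819). Trappc9, which was chosen after its values were seen, fell in CD8 cells when adjusted over the list alone, from 22.5 ± 0.214 to 5.15 ± 1.74 TPM (SD, n = 2). This fall was not set apart from a trend with genomic span. Of 744 genes spanning at least 100 kb, 84.8% were lower in the CD8 KO. Genes of the vesicle coats (adjusted p = 0.873 in CD4 and 0.0650 in CD8) and of Golgi tethering (adjusted p = 0.820 and 0.819), the machinery nearest to TRAPP, were not called by camera either.

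In naive CD4 T cells, 3 of 22 measured targets of the tumour suppressor p53 rose with the knockout. Ccng1, which encodes cyclin G1, went from 156 ± 3.51 to 936 ± 88.9 TPM (SD, n = 2), a log2 difference of 2.58 ± 0.36. Phlda3, a p53-induced inhibitor of Akt signalling, went from 3.76 ± 1.68 to 75.3 ± 0.651 TPM, and Trp53inp1, a p53-induced nuclear protein, from 38.1 and 67.8 to 279 and 281 TPM. The lipid desaturase gene Scd2 rose from 5.08 ± 0.941 to 78.9 ± 3.80 TPM and the ER chaperone gene Calr from 174 ± 32.4 to 788 ± 101 TPM. Among the falls, the DNA repair gene Fanci went from 138 ± 7.64 to 5.15 ± 2.44 TPM and the transcriptional repressor gene Zbtb20 from 181 ± 4.02 to 10.9 ± 0.613 TPM.

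Of the 22 measured p53 targets, 20 were higher in the CD4 KO and 3 passed over all genes, namely Ccng1, Phlda3 and Trp53inp1, the last of these outside the naming rule. Adjusted over the list alone 7 rose, the other members being Bax, Mdm2, Sesn2 and Pmaip1. The median log2 difference of the list was 1.23 and camera called it (adjusted p = 6.35e-09), as did fry (0.0150), while camera gave adjusted p = 0.0767 with an estimated correlation. Psrc1 (log2 difference 3.49 ± 0.61) and Gtse1 (2.61 ± 0.41), both mitotic genes known to respond to p53, rose as well, from 3.48 ± 2.52 to 45.9 ± 12.0 TPM and from 12.5 ± 1.79 to 81.5 ± 14.7 TPM. They are not in the list.

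**Figure D2:**
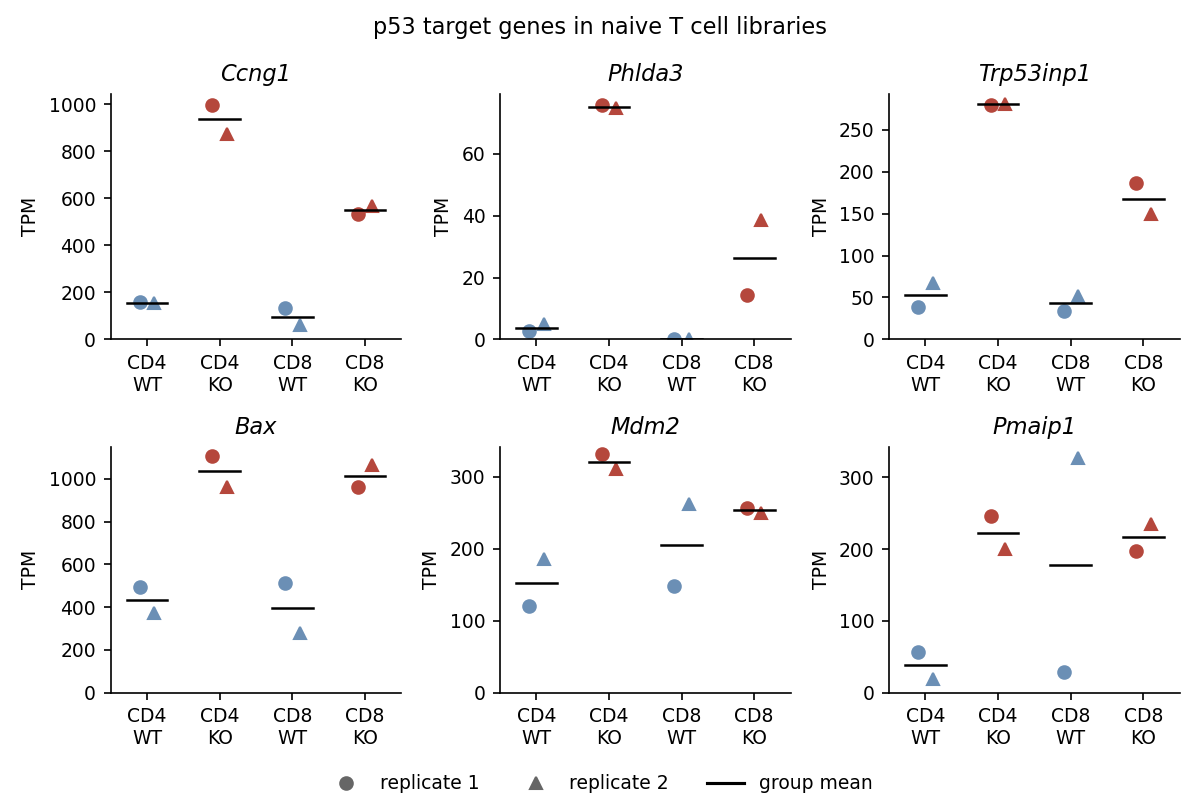
TPM of 6 p53 targets in each library (points, by replicate; red KO, blue WT; bar, group mean of 2 libraries). Both CD4 KO libraries lie above both CD4 WT libraries for each gene shown, as for Ccng1 at 999 and 873 TPM against 158 and 153, while for Pmaip1 and Mdm2 the library labelled CD8 WT replicate 2 lies above both CD8 KO libraries.

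Single genes of cell survival, lipid metabolism and the ER rose in CD4 cells. The pro-survival kinase gene Pim2 rose from 123 ± 10.9 to 555 ± 49.3 TPM, the only one of 15 anti-apoptotic genes to pass over all genes. Of 22 pro-apoptotic genes 0 passed over all genes or over the list alone (limma, 8 at an unadjusted p under 0.05). Scd2 was the single gene to pass in the lists of ferroptosis suppressors (27 measured) and of fatty acid and phospholipid synthesis (25 measured). Adjusted over the list alone, the fatty acid synthase gene Fasn and Chka also rose and Agpat4 fell. Calr was the single gene to pass among 30 ER stress genes, and camera did not call that list (adjusted p = 0.0717). The lactate transporter gene Slc16a1 rose from 17.1 ± 8.26 to 84.0 ± 2.02 TPM, as the single glycolysis gene to pass.

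Among 24 genes of naive T cell survival and quiescence, 17 were lower in the CD4 KO and 1 rose over all genes. That gene was Tob1, an antiproliferative gene, from 27.5 ± 1.04 to 157 ± 31.5 TPM. Adjusted over the list alone 5 fell, among them Il7r, the receptor subunit for the survival cytokine IL-7, from 3070 ± 137 to 1087 ± 122 TPM. The others were Foxp1, Bach2, Rapgef6 and Dapl1. Camera did not call the list (adjusted p = 0.0814). Proximal T cell receptor signalling genes were lower for 22 of 26 members, with a median of -0.46 and 0 past the test (limma, 6 at an unadjusted p under 0.05; camera adjusted p = 0.0553). Of 15 inhibitory receptor and anergy genes, Tox, Nt5e and Cblb fell when adjusted over the list alone (camera adjusted p = 0.0906). The falls in these lists were not set apart from a trend with genomic span. Of 744 genes spanning at least 100 kb, 95.4% were lower in the CD4 KO.

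Camera called 5 further lists in CD4 cells, each toward higher values in the KO. The ribosomal protein genes were higher for 44 of 46 members, with a median of 0.57 (adjusted p = 1.65e-09, and adjusted p = 0.714 with an estimated correlation). Immediate early genes, which include Jun, Fos and Nfkbia and also respond to cell handling, were higher for 20 of 22 members with a median of 1.44, and 1 of them, Nfkbia, rose when adjusted over the list alone (adjusted p = 1.12e-06, and adjusted p = 0.714 with an estimated correlation). T cell activation and effector genes were higher for 31 of 39 members (adjusted p = 1.88e-05, and 0.590 with an estimated correlation). Cell cycle genes were higher for 20 of 32 members (adjusted p = 0.0350, and 0.825 with an estimated correlation). Markers of myeloid cells were higher for 23 of 24 members with a median of 1.87 (adjusted p = 1.46e-06, and 0.714 with an estimated correlation), with Lyz2 at 631 and 926 TPM against 86.9 and 49.0. In these 5 lists 0 members passed over all genes (limma), with 12, 8, 9, 6 and 6 at an unadjusted p under 0.05. Fry alone called cytosolic heat shock genes (adjusted p = 0.0150), of which 12 of 18 were higher and 0 passed by limma (7 at an unadjusted p under 0.05).

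The remaining large changes in CD4 cells fell outside these lists. The gene Kap was listed at 0 in both CD4 WT libraries and stood at 24.0 and 16.7 TPM in the KO. Acat3 went from 0 and 1.15 to 28.5 and 18.1 TPM and is a close copy of Acat2, so its reads are uncertain. Tnfsf4, the ligand of the costimulatory receptor OX40, rose from 4.86 ± 3.16 to 51.4 ± 1.89 TPM and Errfi1, an inhibitor of EGF receptor signalling, from 10.5 ± 2.49 to 74.3 ± 1.96 TPM. Lyrm5, Clybl, Nfyc, Arsb and Cdkal1 fell, with log2 differences of -4.63, -4.27, -3.76, -3.69 and -3.59. The lysosomal sulfatase gene Arsb, for example, went from 35.4 ± 3.66 to 1.84 ± 0.505 TPM. Mir568 went from 68.5 and 69.6 to 3.09 and 0 TPM, and as a gene of 83 bases in a messenger RNA library its level rests on few reads.

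In total limma called 84 of 11786 genes in CD4 cells, 22 higher and 62 lower, all with an absolute log2 difference of at least 1.54. The called falls came from long genes, with 46 of 62 spanning at least 100 kb, against 8.94% of the genes tested. KO and WT libraries did not overlap for 58.1% of the genes, where chance gives 33.3%. The median log2 difference over all genes was -0.16 and moved to 0.03 with median-of-ratios scaling, under which 141 genes were called, 62 higher and 79 lower. With the trend against span removed the balance turned, with 17 genes called, 13 higher and 4 lower. Leaving out the library labelled CD8 WT replicate 2 gave 768 calls, including all 84, and CD8 WT replicate 1 gave 758, while leaving out any of the other 6 libraries gave 0 to 3.

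**Figure D3:**
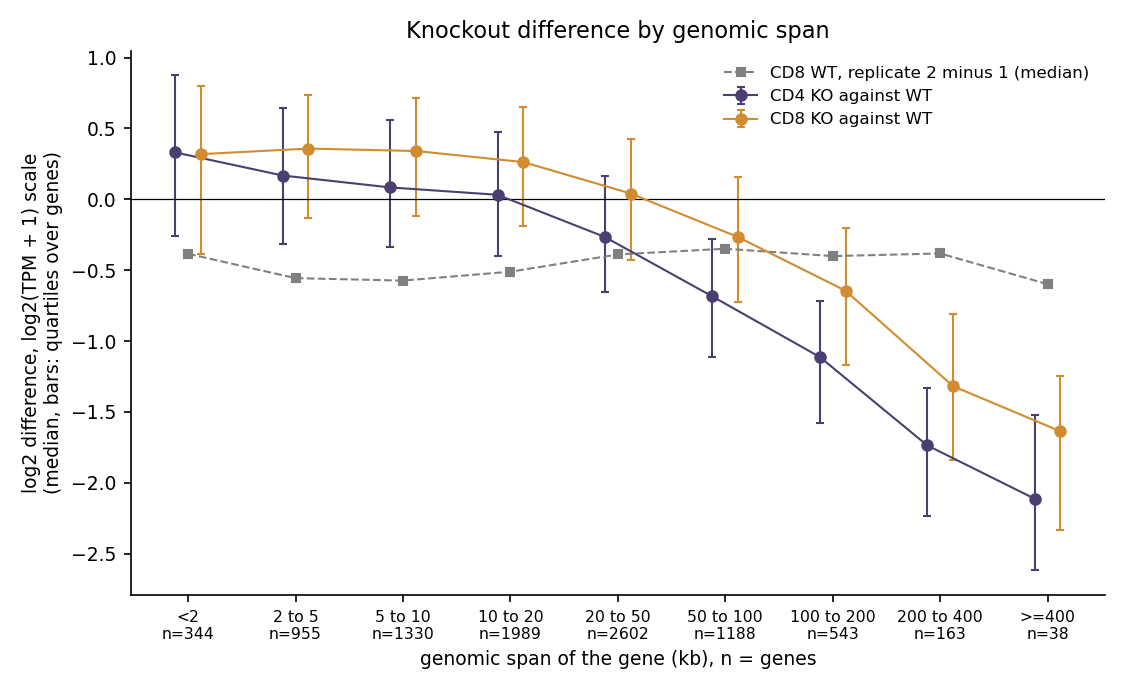
Median log2 difference on the log2(TPM + 1) scale by genomic span in kb, for CD4 (purple) and CD8 (orange) KO against WT, with bars for the quartiles over genes, and in grey the median of CD8 WT replicate 2 minus 1. The CD4 median goes from 0.33 for genes under 2 kb to -2.11 for genes of at least 400 kb, and the CD8 median from 0.32 to -1.64.

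In naive CD8 T cells several of the same genes rose. Phlda3 was listed at 0 in both CD8 WT libraries and stood at 14.3 and 38.6 TPM in the KO, and Ccng1 rose from 132 and 61.4 to 533 and 566 TPM, a log2 difference of 2.59 ± 0.36. Scd2 rose from 4.35 ± 0.456 to 77.1 ± 8.62 TPM (SD, n = 2), Gtse1 from 5.24 ± 2.21 to 63.7 ± 7.07 TPM and Pim2 from 92.6 ± 24.9 to 388 ± 14.4 TPM. The T cell surface gene Cd7 rose from 262 ± 130 to 1425 ± 136 TPM. Falls included Zbtb20, from 137 ± 77.3 to 11.1 ± 1.04 TPM, and the ubiquitin ligase gene Rnf187, from 529 ± 197 to 45.1 ± 0.170 TPM.

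Of the 22 measured p53 targets, 17 were higher in the CD8 KO and 2 passed over all genes, Phlda3 and Ccng1. Adjusted over the list alone 5 rose, with Trp53inp1, Bax and Aen as the others. The list median was 0.47 (camera adjusted p = 0.00602, and adjusted p = 0.790 with an estimated correlation; fry 0.269). Without the library labelled CD8 WT replicate 2 it was 0.88 (4.00e-06, and 0.170 with an estimated correlation), and without CD8 WT replicate 1 the list was not called (0.504). Among pro-apoptotic genes Bad, Bax and Fas rose when adjusted over the list alone, with 0 of 22 past the test over all genes (limma, 7 at an unadjusted p under 0.05; camera adjusted p = 0.124). Nuclear genes of oxidative phosphorylation were higher for 40 of 43 members with a median of 0.54 (adjusted p = 2.82e-06, and adjusted p = 0.921 with an estimated correlation), and 0 passed by limma (7 at an unadjusted p under 0.05). Ribosomal protein genes were higher for 43 of 46 members (adjusted p = 0.000403, and 0.921 with an estimated correlation). Rps2 went the other way and fell from 1205 ± 385 to 240 ± 71.6 TPM, though reads of a gene with many processed copies are uncertain. CD8 lineage markers were higher for 11 of 14 members, with Cd7 called (adjusted p = 0.0427, and 0.921 with an estimated correlation). Without the library labelled CD8 WT replicate 2 the ribosomal list (29 of 46 higher, adjusted p = 0.127) and the CD8 lineage list (7 of 14 higher, adjusted p = 0.423) were no longer called, and the oxidative phosphorylation list was (0.00174, and 0.559 with an estimated correlation).

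Camera called 4 lists toward lower values in the CD8 KO. Immediate early genes were lower for 19 of 22 members (adjusted p = 0.000758), and the phosphatase gene Dusp2 and the early response gene Ier2 fell, from 116 ± 26.9 to 13.5 ± 3.00 TPM and from 824 ± 499 to 114 ± 36.7 TPM. Markers of myeloid cells (22 of 24 lower, adjusted p = 0.000752), B cells (17 of 18 lower, adjusted p = 0.000555) and erythroid cells (12 of 13 lower, adjusted p = 5.96e-06) were the other lists, with 0 members past the test over all genes (limma, 5, 6 and 9 at an unadjusted p under 0.05). Each of these 4 lists had adjusted p = 0.921 with an estimated correlation. Myeloid, B cell and erythroid markers mostly stood higher in the library labelled CD8 WT replicate 2 than in replicate 1. Without it, which leaves 1 CD8 WT library, none of the 4 lists was called. Immediate early, myeloid and B cell genes then had positive medians (0.36, 0.24 and 0.09). The erythroid list stayed lower, with a median of -1.93 and 2 of 13 members higher. Dusp2 still passed (adjusted p = 0.0476) and Ier2 did not (0.0729).

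Other named genes in CD8 cells had log2 differences of 4.30 ± 0.60 for Kap, 4.99 ± 0.61 for Psrc1, and falls with -4.09 for the autophagy gene Uvrag, -4.09 for Gmds, -3.82 for the zinc transporter gene Slc39a11, -3.55 for Rftn2, -3.42 for Cdkal1 and -3.34 for the RNA-binding gene Lsm4. Kap stood at 1.13 and 0 TPM in CD8 WT and at 25.7 and 30.0 in the KO. The scavenger receptor gene Cd163l1 was listed at 0 in both CD8 WT libraries and stood at 48.7 and 35.4 TPM in the KO. Of these genes Gmds still passed without the library labelled CD8 WT replicate 2 (adjusted p = 0.0477), and the others missed with an adjusted p from 0.0510 for Psrc1 to 0.111 for Uvrag. For those without a group at 0 the log2 differences were then 4.35 for Psrc1, 3.76 for Kap, -3.81 for Uvrag, -4.11 for Slc39a11, -3.90 for Rftn2, -3.84 for Cdkal1 and -3.45 for Lsm4.

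In total limma called 35 genes in CD8 cells, 13 higher and 22 lower, with a smallest absolute log2 difference of 2.08, and 6 of them had a library at 0. Libraries did not overlap for 42.1% of the genes, where chance gives 33.3%. Leaving out the library labelled CD8 WT replicate 2 gave 37 calls, of which 15 were among the 35. Without it Scd2, Gtse1, Ccng1, Cd7, Pim2, Zbtb20 and Rnf187 still passed and Phlda3 did not. Phlda3 was listed at 0 in both CD8 WT libraries, so the lost call does not tie its rise to the library left out. Leaving out CD8 WT replicate 1 gave 1842 calls and ended the call of the p53 list (adjusted p = 0.504), and leaving out any other library gave 0. Fits of the CD8 groups alone also gave 0 calls.

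The CD4 and CD8 knockout effects shared called genes. The genes higher in both were Ccng1, Gtse1, Kap, Phlda3, Pim2, Polr2a, Psrc1 and Scd2, which makes 8 of 22 and 13 where 0.0243 are expected from independent lists. The genes lower in both were Cdkal1, Gmds, Slc39a11, Smyd3 and Zbtb20, which makes 5 of 62 and 22 where 0.116 are expected. With the span trend removed 6 rises and 0 falls were shared. Polr2a and Smyd3 stand outside the naming rule. No called gene went in opposite directions. The spread of each gene was pooled over the 8 libraries in both comparisons, which favours genes of low spread in both, so the lists are not independent and no p-value is given. With the compared groups fitted alone 0 calls were shared, as CD8 cells then had 0 calls. Of the 22 genes that rose in CD4 cells 21 were also higher in CD8 cells, and of the 62 that fell 60 were lower. In the reverse direction 12 of the 13 genes that rose in CD8 cells were higher in CD4 cells, and 15 of the 22 that fell were lower. Across all genes, which are not independent replicates, the log2 differences correlated with Pearson's r of 0.285 and Spearman's rho of 0.342, and r was 0.175 with the span trend removed. The comparisons share no library, though the labels do not say whether CD4 and CD8 cells came from the same mice. Without the library labelled CD8 WT replicate 2 the shared calls numbered 20 and r was 0.479. Without CD8 WT replicate 1 they numbered 151 and r was 0.0695, and without any of the other 6 libraries 0 calls were shared.

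The difference between the CD8 and CD4 knockout effects was tested for each gene. Limma called 0 genes, with 819 at an unadjusted p under 0.05 and a lowest adjusted p of 0.367. The lowest p-values belonged to Dusp2 (log2 difference of effects -3.48 ± 0.52), the actin-bundling gene Lcp1 (2.60 ± 0.39) and the TGF-beta receptor gene Tgfbr2 (2.39 ± 0.40), given as values because they did not pass. Lcp1 stood at 681 ± 4.13 TPM in CD4 WT, 262 ± 57.4 in CD4 KO, 472 ± 63.2 in CD8 WT and 1085 ± 30.5 in CD8 KO. Without CD8 WT replicate 1 the count was 1148, with these 3 genes among them. The median over all genes was 0.24 and moved to -0.05 with median-of-ratios scaling.

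WT CD8 and CD4 cells were compared as a check of the lineage labels. Cd4 was lower in CD8 cells by a log2 difference of -5.98 ± 0.66 (adjusted p = 0.00655), at 10.1 ± 6.18 against 654 ± 156 TPM (SD, n = 2). Cd8a and Cd8b1 were higher by 6.07 ± 0.53 and 5.82 ± 0.58 (adjusted p = 0.00345 and 0.00508). Cd40lg, a helper T cell ligand, was lower by a difference of -5.95 ± 0.82 and the surface gene Ly6c1 by -4.09 ± 0.54. The haemoglobin gene Hba-a2 was higher by 5.14 ± 0.78. Without the library labelled CD8 WT replicate 2, which leaves 1 CD8 WT library, Hba-a2 and Ly6c1 were no longer called, while Cd4, Cd8a, Cd8b1 and Cd40lg were. The log2 differences of Hba-a2 and Ly6c1 were then 5.72 and -4.06, so that library did not make them. Hba-a2 stood at 1813 TPM in CD8 WT replicate 1 and at 805 TPM in replicate 2. B cell markers set the cell types apart as well. Cd79b stood at 1116 and 1127 TPM in CD4 WT, 711 and 712 in CD4 KO, and 145 to 249 in the CD8 libraries. Without the library labelled CD8 WT replicate 2 the B cell list had a median of -2.39, with 1 of 18 members higher in CD8 cells. B cell transcripts were thus not confined to that library. The lineage regulators Runx3 (0.76 ± 0.42, adjusted p = 0.615) and Zbtb7b (-2.66 ± 0.93, adjusted p = 0.492) did not pass. Limma called 23 genes, 13 higher and 10 lower, against a median over all genes of -0.26 that moved to 0.02 with median-of-ratios scaling. Camera called 17 lists, and 0 held with an estimated correlation, where the lowest adjusted p was 0.0674 for the CD4 lineage markers. Without the library labelled CD8 WT replicate 2 the count was 72, without CD8 WT replicate 1 it was 1629, without either CD4 WT library it was 0, and without any of the KO libraries it was 11 or 12.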

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

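The tests of what sets the library labelled CD8 WT replicate 2 apart were chosen after the result was seen, and so was the list-by-list account without it, although leaving out each library was planned.

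For 15 gene lists the knockout effect differed between CD8 and CD4 cells in limma's camera test of the difference itself, although 0 single genes did (819 at an unadjusted p under 0.05). None of the 15 held with an estimated correlation, where the lowest adjusted p was 0.577. Immediate early genes led, with 21 of 22 lower in the difference of CD8 minus CD4 effects (median -2.66, adjusted p = 1.22e-14), followed by myeloid markers such as Lyz2 and Ngp (23 of 24 lower, median -3.73, adjusted p = 1.65e-14) and erythroid markers (11 of 13 lower, median -3.54, adjusted p = 4.38e-09). Oxidative phosphorylation genes (38 of 43 higher, median 0.55, adjusted p = 0.00656), T cell receptor signalling genes (24 of 26 higher, median 0.69, adjusted p = 0.00773) and CD8 lineage markers including Cd7 (12 of 14 higher, median 1.07, adjusted p = 0.0161) lay toward CD8 cells. The p53 targets lay lower in the difference, with 8 of 22 higher (median -0.28, adjusted p = 0.0161).

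The other lists that differed all lay lower. They were T cell activation genes (median -0.46, adjusted p = 0.00744), ferroptosis suppressors (-0.35, adjusted p = 0.0189), targets of the stress factor ATF4 (-0.07, adjusted p = 0.0281), anti-apoptotic genes (-0.08, adjusted p = 0.0281), autophagy and lysosome genes (-0.28, adjusted p = 0.0281), ribosomal protein genes (-0.05, adjusted p = 0.0363), cell cycle genes (-0.42, adjusted p = 0.0429) and NK cell markers (-0.60, adjusted p = 0.0454). Without the library labelled CD8 WT replicate 2 the medians of T cell activation (0.07), cell cycle (0.35), NK cell (0.07), ATF4 target (0.23) and autophagy genes (0.04) turned positive. Those of ferroptosis suppressors (-0.09) and anti-apoptotic genes (-0.33) stayed negative. In that setting, which leaves 1 CD8 WT library, 5 lists differed. Immediate early (median -1.01), myeloid (-1.59), erythroid (-1.78) and ribosomal protein genes (-0.43) lay lower, and B cell markers lay higher (0.86). The p53 targets were no longer called, although their median was still -0.23, with 6 of 22 higher. With an estimated correlation the 5 lists did not pass either, at 0.438, 0.629, 0.493, 0.884 and 0.438 in the order given.

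The library labelled CD8 WT replicate 2 differed from replicate 1 in markers of other cells. Its myeloid markers lay higher by a median log2 difference of 4.15 (23 of 24 members, with Ngp at 17333 TPM), erythroid markers by 4.74 (12 of 13) and B cell markers by 2.39 (17 of 18), while 23 of 26 T cell receptor signalling genes lay lower. RNA from myeloid and erythroid cells is therefore a candidate explanation, as a hypothesis, although the sort gate on CD62L and CD44 with CD4 or CD8 should exclude such cells. The B cell marker Cd79b went the other way, at 0.662 times replicate 1. Hba-a2 was at 0.444 times replicate 1 while its near-identical copy Hba-a1 was at 2320 times, and the division of their reads is uncertain. Hba-a2 therefore does not count against erythroid RNA. The haemoglobin gene Hbb-b1 was at 120 times replicate 1. A mislabelled CD4 library is argued against, since Cd8b1 exceeded Cd4 by 45.4 times. A mislabelled KO library is argued against only weakly. Scd2 was at 4.03 TPM where the lowest KO library had 71.0 and CD4 WT had 4.42 and 5.75. Scd2 was picked after its values were seen, and the CD8 comparison that called it counted this library as WT. Trappc1, at 40.3 TPM as deposited, lay below both CD8 KO libraries (56.9 and 45.6). No biological explanation was tested, since both libraries carry the same group label.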

How the results depend on the processing

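The block on replicate numbers, the filter, the pseudocount and the left-out libraries were planned; FPKM, both rescalings, library weights and the removal of the span trend were chosen after the data were seen. Settings fixed in advance that need read counts (another count tool and its size factors) were not run because the files hold none, and the planned stricter filter is the filter already used. Unless given here, counts stayed within 1.5 times. The cause was not tested except where stated.

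Main counts were 84 genes in CD4, 35 in CD8, 0 for the difference of effects, 23 for WT CD8 against CD4, and 13 shared. Without a filter on low values they were 0, 0, 0, 1 and 0, with 10 lists in CD4 and 8 for the difference in place of 6 and 15. With the compared groups alone CD4 gave 243 genes and 11 lists, CD8 0, WT 0 and shared calls 0. Library weights gave 1260 in CD4, 0 in CD8, 15 for WT and 0 shared. Median-of-ratios scaling gave 141 in CD4. Removing the span trend, which takes out the differences of long genes by construction, gave 17 in CD4 (13 higher, 4 lower; 16 of the 84), 21 in CD8 (12 higher, 9 lower; 20 of the 35) and 6 shared, all higher, so the 5 shared falls were gone, with r of 0.175 in place of 0.285. The rank correlations with span became -0.0373 and -0.0466. A pseudocount of 0.1 left 8 shared. With an estimated correlation 0 lists passed in each of the 4 comparisons, and fry called 2, 0, 0 and 3.

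With the replicate number as a block, CD4 gave 29 genes, CD8 26, the difference 0, WT 26 and shared calls 7, and with the block nested in genotype the difference gave 1 gene and WT 24. Libraries of the same number did not deviate together, with correlations across genes of -0.0359 to 0.0942, so the numbers are not read as pairs.

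Leaving out each library in turn gave 0 to 768 genes in CD4, 0 to 1842 in CD8, 0 to 1148 for the difference, 0 to 1629 for WT and 0 to 151 shared, with r of 0.0695 to 0.479. Lists numbered 6 to 13, 6 to 14, 5 to 18 and 12 to 20. The CD4 count was high without either CD8 WT library (758 and 768), which takes the difference between these, the least alike replicates (r of 0.821), out of the pooled spread by construction. The other highest counts came without CD8 WT replicate 1, when replicate 2 alone stands for CD8 WT; without replicate 2 they were 37, 0, 72 and 20. A group left with 1 library is assumed to vary like the others. The p53 list had adjusted p of 2.29e-10 to 1.48e-06 in CD4 and 4.00e-06 to 0.504 in CD8, and the rank correlation with span was -0.484 to -0.406 and -0.356 to -0.297.

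Of 961 repeats of a named gene, 528 kept direction and call, 424 lost the call, 4 gained one and 5 changed sign. The gains were Trappc1 in CD4 with library weights (adjusted p = 0.0440) and, for the difference of effects without CD8 WT replicate 1, Dusp2 (0.0108), Lcp1 (0.00700) and Tgfbr2 (0.0108). The changes of sign were for Trappc1, which passed in none of these. For WT CD8 against CD4 its log2 difference became 0.06 without CD4 WT replicate 1, 0.30 without CD8 WT replicate 2, 0.10 with median-of-ratios 0.0147 with quantile scaling and -0.70 without CD8 WT replicate 1. For CD8 KO it was 0.33 without CD8 WT replicate 1 and -0.66 without replicate 2. List medians near 0 (vesicle coats, Golgi, ATF4 targets, fatty acid synthesis, interferon and thymic emigrant genes in CD4; Golgi, cholesterol synthesis, interferon and NK genes in CD8) changed sign with scaling. Depth of 3.03 to 4.01 gigabases and 2 libraries a group limit detection to large changes.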

Other observations

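The tests on genomic span, the permutations of library scores and the list-by-list account without a library were chosen after the result was seen, as were the genes named. The p53 list with its estimated correlation, the left-out libraries and the test with a myeloid score were planned.

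When the library labelled CD8 WT replicate 2 was left out, further members of the lists passed in CD4 cells (limma, adjusted over all genes). The CD4 libraries and their log2 differences are unchanged in this setting, so the added calls come from a smaller pooled spread. CD8 WT then has 1 library, which is assumed to vary like the others. Among p53 targets 10 rose, including the cell cycle inhibitor Cdkn1a, the p53 regulator Mdm2 and the death genes Bax and Pmaip1 (list adjusted p = 2.55e-10, and adjusted p = 0.127 with an estimated correlation). Among immediate early genes 10 rose, including Jun, from 28.4 and 30.2 to 315 and 269 TPM, and Fos, from 7.14 and 7.14 to 63.6 and 58.2 TPM (list adjusted p = 2.51e-11, and 0.133 with an estimated correlation). Of the naive survival genes 7 fell, among them Il7r, Lef1, Satb1 and Bach2, and Ccr7 and Tob1 rose (list adjusted p = 0.0441, and 0.443 with an estimated correlation). The falls of naive survival genes were not set apart from the trend with genomic span. Markers of other cells moved along, with B cell markers falling and the myeloid markers C1qb, Cd68, Lyz2, S100a8 and S100a9 rising. The list medians were -0.78 for B cell and 1.87 for myeloid markers. The T cell receptor signalling genes Grap2, Ptpn22, Ptprc and Themis fell (list median -0.46). The ER chaperone gene Hspa5 and the stress regulators Atf4 and Ddit3 rose as well, but their lists as a whole hardly moved. Of the ER stress genes 17 of 30 were higher (median 0.05), and of the ATF4 targets 11 of 23 (median -0.02). With all libraries camera called neither list (adjusted p = 0.0717 and 0.303). In CD8 cells 7 lists were called. Ccng1 and Plk2 rose among p53 targets (list adjusted p = 4.00e-06, and 0.170 with an estimated correlation), and naive survival genes lay lower for 20 of 24 members with 0 past the test (adjusted p = 5.43e-05, and 0.506 with an estimated correlation). T cell activation genes (30 of 39, adjusted p = 4.00e-06, and 0.170 with an estimated correlation), cell cycle genes (28 of 32, 3.04e-05, and 0.506), oxidative phosphorylation genes (33 of 43, 0.00174, and 0.559), ER stress genes (22 of 30, 0.0111, and 0.448) and ATF4 targets (18 of 23, 0.0111, and 0.518) lay higher.

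Sex-linked genes were unevenly spread over the genotypes, and of these the Y-linked gene Uty fell in CD4 cells (limma, adjusted p = 0.0343). Xist, transcribed from the inactive X chromosome of females, was listed at 0 and 0.0115 TPM in CD4 WT, 8.30 and 8.27 in CD4 KO, 0.259 and 3.80 in CD8 WT, and 7.69 and 7.35 in CD8 KO. Uty stood at 39.2 and 40.6, 5.03 and 4.01, 22.6 and 15.7, and 10.1 and 6.16 TPM in the same order. As Uty spans 149 kb, its fall was not set apart from the trend with genomic span. Each KO library held Xist together with Y-linked transcripts, with Ddx3y at 111 to 147 TPM, while CD4 WT held Y-linked transcripts and almost no Xist. Whether libraries pooled mice of both sexes was not tested. The ferritin gene Ftl1, which has many processed copies, stood at 11029 and 6855 TPM in CD4 WT and 21531 and 16546 in CD4 KO (adjusted p = 0.233). Within 20 Mb of Trappc1 on chromosome 11, 5 of 445 tested genes were called in CD4 cells, of 84 in all.

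Genes that span more of the genome were lower in both knockouts. Over 9152 genes with a mean of at least 5 TPM, the log2 difference and span had rank correlations of -0.467 in CD4 and -0.350 in CD8, and of -0.329 against CD8 WT replicate 1 alone. Differences between replicates gave -0.133 to 0.212. A bias with mature transcript length is argued against, since the CD4 correlation given that length was -0.485 (87.9% of genes had a length). Dilution by RNA of other cells as the whole cause is argued against too. A set of 8 short T cell receptor signalling genes had a CD4 median of -0.32, higher by 0.981 than that of genes of at least 100 kb. It lay below the medians of all genes under 20 kb, which were 0.03 to 0.33 by span class, so partial dilution is not excluded. Preparation differing between genotypes cannot be told apart from the knockout, because the design has no library in which they part. A score of long minus short genes put the 4 KO libraries below the 4 WT libraries (exact two-sided permutation p = 0.0286, and 0.0556 with genotype permuted within cell type, each the smallest possible). This restates the pattern and says nothing of its cause. Sex-linked genes largely followed the genotype. In the library labelled CD8 WT replicate 2, Xist (3.80 TPM) lay between replicate 1 (0.259) and the KO libraries (7.35 to 8.30). Its Uty and Ddx3y (15.7 and 168 TPM) lay above all KO libraries, and its Eif2s3y and Kdm5d (53.9 and 6.76 TPM) lay among them. The score of long minus short genes in that library was 0.510, beside 0.568 in replicate 1 and apart from -0.857 to -0.440 in the KO libraries. As 1 library with intermediate sex-linked genes and markers of other cells, it neither parts sex from the genotype nor settles sex as a cause. A fall in transcripts of long genes may be biological only as a hypothesis.

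The p53 targets were higher in both knockouts and could reflect RNA of other cells or the span trend. With a myeloid score as a covariate the list had adjusted p = 1.58e-06 in CD4 and 1.60e-05 in CD8 cells. The score is the mean of the myeloid list itself. That list's own value of 0.623 in CD4 therefore followed by construction and decides nothing. Within groups the score differed most between the CD8 WT libraries (-0.596 and 3.39), so its slope rests mostly on these. Within that limit, the call kept by the p53 list argues against myeloid RNA as the whole cause. With the span trend removed the p53 list had adjusted p = 1.63e-08 in CD4 and 0.0169 in CD8. These values use the preset correlation; without a correction the list missed with an estimated correlation (0.0767 in CD4, 0.790 in CD8), and in CD8 it also missed without CD8 WT replicate 1 (0.504). Preparation cannot be told apart from the genotype by design here either. In the library labelled CD8 WT replicate 2, Xist and Uty lay between the other WT and the KO libraries. The mean score of the p53 list in that library was 0.0865. It was -0.853 in replicate 1 and 0.234 to 0.818 in the KO libraries, so that 1 library does not settle sex as a cause. The score of the list set the KO above the WT libraries (exact two-sided permutation p = 0.0286, and 0.0556 within cell type, each the smallest possible), which restates the rise. That the rise of Ccng1, Phlda3 and Bax and the fall of long genes such as Zbtb20 and Foxp1 share an origin in stressed cells is a hypothesis that these data do not test.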
